A study of Mus musculus with 10 samples.

How the data were processed

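RNA was sequenced from kidney cells held back by magnetic beads against F4/80, a surface protein of mouse macrophages encoded by Adgre1. Per the labels' protocols, perfused kidneys were minced, digested with an enzyme mix for 30 minutes and passed through a 40 µm mesh, dead cells were removed, and live cells were then selected with the beads. Libraries were prepared from 75 ng of total RNA after oligo-dT enrichment with a strand-specific kit. The mice were 4 heterozygotes for the C105F substitution in Umod, made by genome editing in C57BL/6J embryos, and 6 wild-type littermates, all between 12 and 16 weeks of age. The labels describe separate mice, so the spread between libraries includes the spread between animals.

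The authors deposited 1 table with estimated read counts and FPKM values for each RefSeq transcript in each library. Per the submitters' processing notes, the tools were Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1, StringTie 1.3.4d and DESeq2, with the genome build mm10; which tool did which step is not given in the sources used here. The deposited estimated counts are whole numbers that are not scaled for depth. They equalled FPKM times transcript length times 1 constant per library, within 1 read or 0.5%, for 100% of transcripts with at least 20 counts. Both columns therefore hold the same estimate, which would be so for any way of assigning reads. How reads of overlapping transcripts and of near-identical genes were apportioned is not given, and genes of such families are less certain. The deposited FPKM values, which the authors scaled for transcript length and library depth, were used only for this comparison. The table had 36779 transcripts of 24541 gene symbols, and 1 further line was empty. Coordinates are 1-based on mm10, as the table gives them, and span all transcripts of a gene.

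Estimated counts, already whole, were summed per gene symbol. Library totals lay between 45380415 and 73643200, a ratio of 1.62. Genes were filtered with filterByExpr and scaled by TMM, and 15123 genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. CPM values are TMM-scaled throughout, and log2 CPM used a prior count of 2. The level of Umod was also compared by a two-sided exact permutation test over the 210 assignments of 4 of the 10 libraries, whose smallest possible p is 0.00476. By chance 0.95% of genes would have all mutant libraries above, or all below, all wild-type libraries.

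A set of 40 gene lists, 16 of them cell type markers, was fixed before the data were examined, as were the tests, the groups and the rule for named genes. The lists were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 40 lists, and again with an estimated correlation. The rotation test fry asked whether the genes of a list moved, on balance, 1 way. A score per library, the mean log2 CPM of the members with each gene centred on its mean over all 10 libraries, was compared by the exact permutation test. A total of 6 list members, all immunoglobulin or T cell receptor constant genes, had no row. The rule names Umod, the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1, filled up by smallest p, and the 3 members of each list with the smallest p. Adgre1, Atf4 and called genes outside the rule were named after their values were seen, and 2 genes that the rule names are not reported here.

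The test was tried on counts simulated from the means, dispersions and totals of these libraries, with 15123 genes and 4 mutant against 6 wild-type libraries. It recovered 78.0% of 50 genes raised 4-fold, 36.0% of 50 genes raised 2-fold, 74.0% of 50 genes lowered to 0.25 and 36.0% of 50 lowered to 0.5 of their level, and 2.6% of its calls were unchanged genes. Changes of about 2-fold in single genes are therefore often missed at this number of mice. The simulated genes varied independently of each other, and only genes above a count minimum were changed. Variation that genes share between libraries was left out, so the shares recovered and falsely called may not hold in the real libraries. No pair of libraries of a group was a duplicate: the smallest chi-square per gene between 2 libraries was 74.9.

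Alternatives planned before the data were examined were other scalings, filters and tests (DESeq2 1.42.0, limma 3.58.1), tests on single transcripts, a replicate block, a tubule marker score as covariate and leaving out each library. Alternatives chosen after seeing the data were covariates for a macrophage and an ascending limb marker score, fits without the 2 libraries of each group with the lowest Adgre1, a fit of the 8 libraries with shared replicate numbers, and a table without Rn45s. Figures were drawn with matplotlib 3.10.9.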

Results

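The data were 10 RNA-seq libraries of F4/80-selected kidney cells, 4 from mice heterozygous for the C105F substitution in uromodulin and 6 from wild-type littermates. Uromodulin, encoded by Umod, is a protein that cells of the thick ascending limb secrete into urine. The study asked whether gene expression in kidney macrophages differs in mice that carry the mutation. Total estimated counts ran from 45380415 in mutant replicate 5 to 73643200 in wild-type replicate 5.

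The most abundant RNAs in the selected cells were those of kidney tubules. Kap, an androgen-regulated gene of the proximal tubule, averaged 31747 CPM over the 10 libraries, Gpx3, a secreted peroxidase of the proximal tubule, averaged 23085 CPM, and Slc34a1, the proximal tubule phosphate transporter, averaged 5562 CPM. Adgre1, which encodes F4/80 and was singled out after its values were seen, averaged 192 CPM and ranked 946 of 15123 genes. It differed 58.6-fold between libraries, from 14.0 CPM in wild-type replicate 1 to 819 CPM in mutant replicate 5. The group means of Adgre1 were 291 ± 361 CPM in mutants (SD, n = 4) and 126 ± 145 CPM in wild type (SD, n = 6), with overlapping groups and an edgeR adjusted p of 0.959. Cd74, the invariant chain of MHC class II, averaged 3126 CPM.

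**Figure D1:**
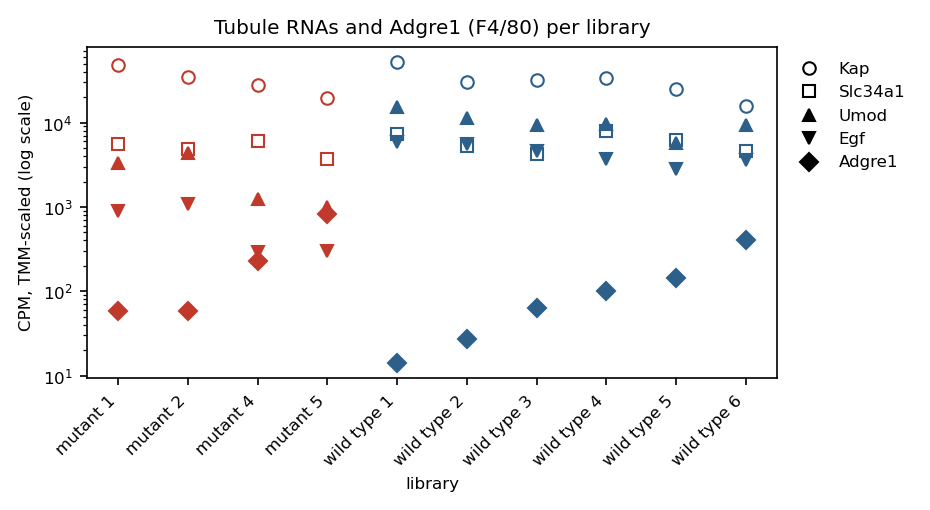
TMM-scaled CPM (log axis) of the tubule RNAs Kap, Slc34a1, Umod and Egf and of Adgre1 in each of the 4 mutant (red) and 6 wild-type (blue) libraries, 1 point per gene and library. Adgre1 runs from 14.0 to 819 CPM, and Slc34a1 from 3659 to 7841 CPM.

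The largest difference between libraries ran along macrophage markers. The first principal component held 45.6% of the variance of log2 CPM and followed a score of resident macrophage markers over the 10 libraries (Pearson r = 0.97, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.94, permutation p = 2e-04). Without the 2 libraries farthest from the median score r was 0.92, and within the 6 wild-type libraries it was 0.97. The markers also enter the component, so the measures are not independent. The macrophage score was -0.48, -0.51, 0.74 and 2.12 in mutant replicates 1, 2, 4 and 5.

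Umod (gene 22242, chromosome 7, 119462708 to 119479262) was measured first, as the edited gene. Its RNA averaged 2470 ± 1615 CPM in mutants (SD, n = 4) and 10076 ± 3056 CPM in wild type (SD, n = 6), with each mutant library below each wild-type library. The log2 fold change was -2.03 (SE 0.445), with a two-sided exact permutation p of 0.00476, the smallest that 4 against 6 libraries allow. Over all genes tested it did not pass, with an edgeR adjusted p of 0.184. It passed with the macrophage score as covariate (log2 fold change -1.84, adjusted p = 0.016), without the 2 libraries of each group with the lowest Adgre1 (-2.95, adjusted p = 0.0474) and in DESeq2 (-2.03, adjusted p = 0.000229). It also passed with a replicate block over 4 shared numbers (-2.27, edgeR adjusted p = 0.0181), against 0.396 in the same 8 libraries without the block. Over the alternatives the adjusted p ranged from 0.000229 to 0.4. The substitution changes 1 amino acid, so the RNA level does not check the genotype labels.

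Genes of the integrated stress response, the program that the transcription factor ATF4 drives when translation is restrained, were higher in the mutant libraries. Trib3, a pseudokinase induced by ATF4 (gene 228775, chromosome 2, 152337425 to 152344060), rose from 0.712 ± 0.252 CPM in wild type (SD, n = 6) to 38.4 ± 17.4 CPM in mutants (SD, n = 4), a log2 fold change of 5.75 (SE 0.377, edgeR adjusted p = 0.000151). Atf5, a related transcription factor (gene 107503, chromosome 7, 44812256 to 44816658), rose from 14.3 ± 3.45 to 110 ± 32.3 CPM, a log2 fold change of 2.95 (SE 0.22, adjusted p = 0.00029). Asns, asparagine synthetase (gene 27053, chromosome 6, 7675171 to 7693182), rose by 2.86 on the log2 scale (SE 0.26, adjusted p = 0.00111). Ddit3, which encodes CHOP, rose by 1.74 and Chac1, a glutathione-degrading enzyme, by 3.25.

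In all, 27 genes rose and 3 fell in mutants among 15123 tested, and 892 had an unadjusted p under 0.05. The integrated stress response list had 32 tested members, of which 8 rose and 18 passed when adjusted over the list alone: Trib3, Atf5, Asns, Ddit3, Chac1, Slc7a5, Mthfd2 and Aldh1l2 passed over all genes. The median log2 fold change of the list was 0.97 (camera adjusted p = 1.45e-59; adjusted p = 0.000331 with an estimated correlation), and its fry adjusted p was 0.000203. The score of the list per library had an exact permutation p of 0.00476, the smallest possible, and of 0.0952 when adjusted over all lists. No list passed the exact permutation test after that adjustment. Atf4 itself, named after its values were seen, averaged 129 ± 14.3 CPM in mutants (SD, n = 4) and 64.3 ± 14.3 CPM in wild type (SD, n = 6), with an edgeR adjusted p of 0.0575.

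**Figure D2:**
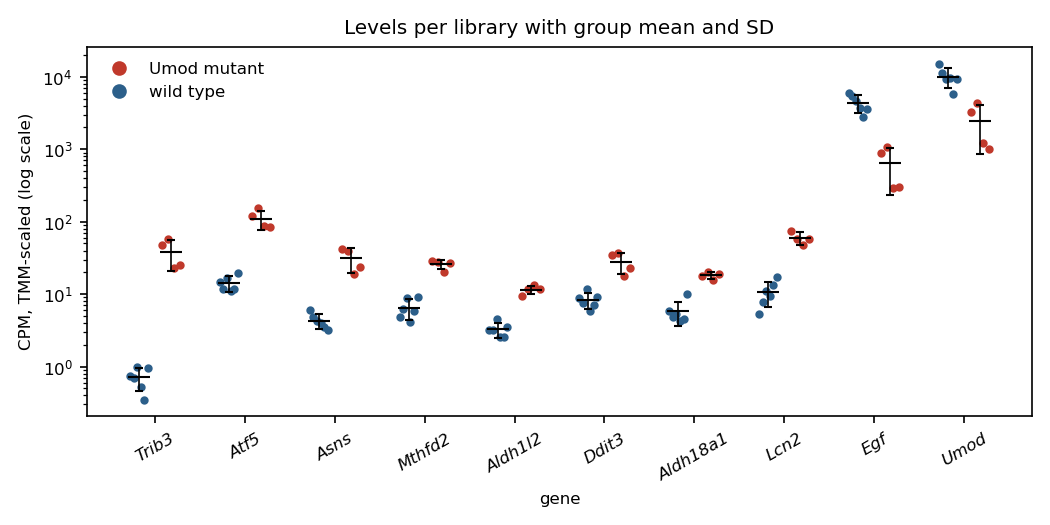
TMM-scaled CPM (log axis) of 10 genes in the 4 mutant (red) and 6 wild-type (blue) libraries, 1 point per library, with the group mean as a bar and the SD as whiskers. All mutant points of Trib3 lie above all wild-type points, with means of 38.4 and 0.712 CPM, and all mutant points of Egf and Umod lie below them.

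Enzymes that make amino acids and one-carbon units rose in part. Of 18 members of the serine, proline and one-carbon list, 4 rose and 6 passed when adjusted over the list alone. These 4 were Asns, the mitochondrial folate enzymes Mthfd2 (log2 fold change 1.98, SE 0.235) and Aldh1l2 (1.82, SE 0.195), and Aldh18a1, the first enzyme of proline synthesis (1.66, SE 0.232). The other members went both ways, 10 of 18 fold changes were positive and the median was 0.11 (camera adjusted p = 1.81e-09; adjusted p = 0.0962 with an estimated correlation). That median was 0.02 without mutant replicate 1, -0.01 without mutant replicate 2, and 0.18, 0.07 and 0.05 without wild-type replicates 1, 5 and 6. Of 20 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 19 had positive fold changes with a median of 0.26, and 0 passed over all genes in edgeR or when adjusted over the list alone (camera adjusted p = 2.85e-07; adjusted p = 0.197 with an estimated correlation). Gars, Nars and Aars had log2 fold changes of 0.30, 0.32 and 0.35. Slc7a5 and Slc7a3, amino acid transporters, both rose; Slc7a3 had 4 counts in all 6 wild-type libraries together and 653 in the 4 mutants.

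Chaperones of the endoplasmic reticulum did not pass. The list of 25 chaperone and unfolded protein response genes had 0 called members in edgeR and a median log2 fold change of 0.09 (camera adjusted p = 0.236; adjusted p = 0.67 with an estimated correlation). Hspa5, the chaperone BiP, had a log2 fold change of 0.40 (SE 0.237, edgeR adjusted p = 0.958), Xbp1 0.27 (SE 0.154) and Derl3 -1.04 (SE 0.483).

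Markers of tubular injury were higher in mutants. All 11 tested members had positive fold changes, with a median of 0.73, 1 rose and 3 passed when adjusted over the list alone (camera adjusted p = 4.5e-11; adjusted p = 0.00389 with an estimated correlation). The score of the list had an exact permutation p of 0.0143, and of 0.114 when adjusted over all lists, which did not pass. Without wild-type replicate 6 the median was 1.25. The called member was Lcn2, encoding the secreted iron-siderophore carrier NGAL (gene 16819, chromosome 2, 32384637 to 32387739), which rose from 10.7 ± 4.15 CPM in wild type (SD, n = 6) to 59.6 ± 11.5 CPM in mutants (SD, n = 4; log2 fold change 2.48, SE 0.28, edgeR adjusted p = 0.00473). Sox9, a transcription factor of regenerating tubules, had a log2 fold change of 1.76 and Clu, clusterin, of 0.64, neither called.

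Other called rises lay outside the lists. Akr1b8, an aldo-keto reductase, rose by 3.11 on the log2 scale (SE 0.251), Wnt10a by 3.10 (SE 0.335), Tenm4, a teneurin, by 1.79 (SE 0.212) and Cbr3, a carbonyl reductase, by 1.71 (SE 0.265). The neurofilament genes Nefm and Nefl, named after their values were seen, rose by 3.19 and 3.09. Areg, which encodes the EGF receptor ligand amphiregulin and was also named after its values were seen, had 11 counts in the 6 wild-type libraries and 1103 in the 4 mutants. Ostn and Npffr2, likewise outside the rule, had 0 counts in all 6 wild-type libraries and were at least 303-fold and at least 119-fold higher in mutants, against a floor of 3 counts over the wild-type group that covers counting error only.

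The 3 genes that fell were Egf, Fam107a and Ifit1bl1. Egf, the precursor of epidermal growth factor made in the ascending limb and distal tubule (gene 13645, chromosome 3, 129677577 to 129755322), fell from 4345 ± 1210 CPM in wild type (SD, n = 6) to 639 ± 404 CPM in mutants (SD, n = 4; log2 fold change -2.77, SE 0.441, edgeR adjusted p = 0.0345). Fam107a fell by 1.64 (SE 0.212) and Ifit1bl1, named after its values were seen, by 1.80 (SE 0.275). The next genes by p did not pass: Rhof, Stk32b, Wnt11, Slc9a3, Irx1, Arhgap29, Perm1, Lmo1, Prss12 and Etnk1 had log2 fold changes of -1.65, -0.95, -1.13, -1.03, -1.06, -0.44, -1.50, -1.34, -1.13 and -0.57. Of 13 thick ascending limb and distal tubule markers 1 fell and 3 passed when adjusted over the list alone, with a median of -0.28 (camera adjusted p = 2.25e-08; adjusted p = 0.203 with an estimated correlation). Without mutant replicate 2 that median was -0.52. Ppp1r1a had a log2 fold change of -0.87.

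The count of 30 fell to 14 without mutant replicate 1, 19 without mutant replicate 5, 13 on single transcripts and 13 without the 2 libraries of each group with the lowest Adgre1, and rose to 50 with the macrophage score as covariate and 143 in DESeq2, where 69 rose and 74 fell. In the 10 fits without 1 library, 14 of the 30 genes kept their call each time (Trib3, Atf5, Asns, Mthfd2, Aldh1l2, Chac1, Slc7a3, Lcn2, Akr1b8, Wnt10a, Tenm4, Nefm, Nefl and Areg), while Slc7a5 and Fam107a kept it in 9, Ddit3 in 7, Ostn in 6, Cbr3 and Aldh18a1 in 3, Ifit1bl1 in 2, Egf in 1 (adjusted p up to 0.0981) and Npffr2 in 0.

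Lists of macrophage markers, T cell markers and immune pathways had positive medians but no called members, while those of neutrophils and of eosinophils, mast cells and basophils had medians of -0.53 and -0.58. The macrophage score was on average 0.78 higher in mutants, within the spread between libraries (exact permutation p = 0.319), and the positive lists moved with it. The median log2 fold change was 1.07 for 15 resident macrophage markers, 1.07 for 20 chemokines, 1.07 for 13 complement genes, 0.97 for 12 MHC class II genes, 0.89 for 16 alternative activation genes, 0.78 for 22 phagocytic and scavenger receptors, 0.70 for 16 interferon gamma genes, 0.66 for 22 type I interferon genes, 0.53 for 21 NF-kB genes, 0.48 for 14 T cell markers and 0.34 for 24 fibrosis-related macrophage genes. Each of these lists passed camera with the preset correlation, and none did with an estimated one, where the adjusted p was 0.549 for chemokines and 0.649 for the others. Over all genes 0 members passed in edgeR, and 1 chemokine passed when adjusted over the list alone. Without mutant replicate 5 the medians of these lists lay between -0.31 and 0.24, and chemokines alone kept their call (0.08, camera adjusted p = 0.0164); without wild-type replicate 6 all but the T cell list rose over 1.5 times, to between 0.70 and 1.83. MHC class II also lost its call without mutant replicate 4 or wild-type replicate 1 or 2 (medians 1.04, 0.75 and 0.77), and complement without wild-type replicate 1 or 2 (0.85 and 0.86). T cell markers lost theirs without mutant replicate 4 or wild-type replicate 1, 2, 4 or 5 (0.22, 0.40, 0.42, 0.30 and 0.47) and were at 0.80 without wild-type replicate 3, and the fibrosis-related list was at 0.17, 0.16 and 0.22 without wild-type replicates 1, 2 and 4.

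Among single immune genes, Cxcl10, an interferon-induced chemokine, came nearest, with 25.8 ± 10.6 CPM in mutants (SD, n = 4) and 6.47 ± 3.93 CPM in wild type (SD, n = 6; log2 fold change 2.0, SE 0.439, edgeR adjusted p = 0.184) and all mutant libraries above all wild-type libraries. The scavenger receptor genes Trem2, Cd163 and Mrc1 had log2 fold changes of 2.22, 2.90 and 2.09 with SE of 0.886, 1.17 and 0.991, and their groups overlapped. H2-Eb1, an MHC class II chain, had 1.02 (SE 0.83) and became -0.14 without mutant replicate 5, 1.7 without wild-type replicate 6, -0.10 with the macrophage score as covariate and -0.65 with the tubule or the ascending limb score. Without mutant replicate 5, 12 lists passed in place of 24.

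**Figure D3:**
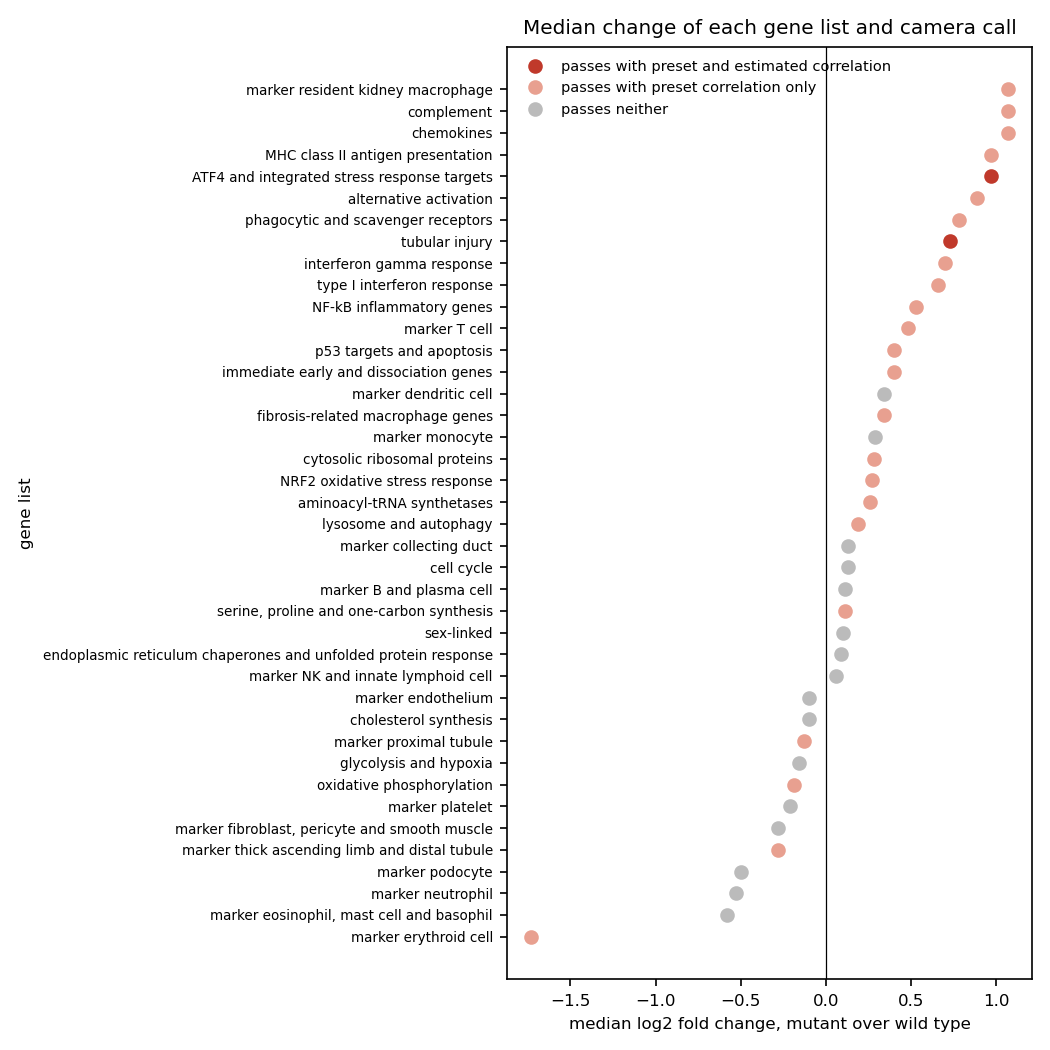
Median log2 fold change, mutant over wild type, of the tested members of each of 40 gene lists, with colour for the camera result. The integrated stress response list, at 0.97, and the tubular injury list, at 0.73, are the 2 that pass with both the preset and the estimated correlation.

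Of the other lists, 8 passed with the preset correlation and lost it with an estimated one. The NRF2 oxidative stress list had a median of 0.27 and 4 of 13 members that passed when adjusted over the list alone (camera adjusted p = 0.000401; adjusted p = 0.203 with an estimated correlation), and its median was 0.17 without wild-type replicate 5. Hmox1, heme oxygenase 1, had 0.77, Srxn1 0.46 and Slc7a11, the cystine transporter, 2.77, all with every mutant library above every wild-type library. None of them was called, and separation tells less for members picked by smallest p. Slc7a11 averaged only 0.414 CPM in wild type (edgeR adjusted p = 0.495). The p53 list had a median of 0.40, 2 of 16 members that passed over the list alone and Cdkn1a, which encodes the cell cycle inhibitor p21, at 1.37 (adjusted p = 0.197 with an estimated correlation). Its median was 0.18 without mutant replicate 5 and 0.13 with the tubule score as covariate. Medians were 0.40 for immediate early and dissociation genes (adjusted p = 0.51 with an estimated correlation), 0.28 for ribosomal proteins (0.564), 0.19 for lysosome and autophagy genes (0.649), -0.19 for oxidative phosphorylation (0.67), -0.13 for proximal tubule markers (0.649) and -1.73 for erythroid markers (0.203), each as the adjusted p with an estimated correlation. Leaving out 1 library moved each of these medians. Immediate early genes were at 0.24 without mutant replicate 1 and 0.68 without wild-type replicate 2, and ribosomal proteins at 0.17 without mutant replicate 2. Lysosome genes lost their call without mutant replicate 5 (median 0.04) or 2 (0.14) or wild-type replicate 2 (0.14) or 3 (0.20). Oxidative phosphorylation lost it without mutant replicate 4 (-0.07) or 5 (-0.01) or wild-type replicate 1 (-0.03), and was at -0.34 without mutant replicate 2. Proximal tubule markers lost it without mutant replicate 5 (0.01) or wild-type replicate 1 (-0.16), 4 (-0.06) or 5 (-0.10), and were at -0.22, -0.22 and -0.21 without mutant replicates 1 and 4 and wild-type replicate 6. Erythroid markers were at -0.60, -1.07, -0.93 and -0.71 without wild-type replicates 1, 2, 3 and 6, with the call kept.

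The lists that passed neither test included cell cycle genes (median 0.13), glycolysis and hypoxia (-0.16) and cholesterol synthesis (-0.10). The granulocyte lists above were among them, and the other cell type markers that passed neither had medians of 0.29 for monocytes, 0.34 for dendritic cells, 0.06 for NK and innate lymphoid cells, 0.11 for B and plasma cells, 0.13 for collecting duct, -0.50 for podocytes, -0.10 for endothelium, -0.28 for fibroblasts, pericytes and smooth muscle and -0.21 for platelets. The sex-linked list had a median of 0.10, and all 10 libraries held RNA of the Y-linked gene Ddx3y and 0 held Xist.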

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

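Of the tests here, those on marker slopes, on covariates, on the immune lists without single libraries and on the ascending limb markers were chosen after the results were seen; the counts over other splits of the libraries were planned. A library stood far from the rest of its group in 8 of 130 groups screened, where chance gives about 1 in 20. Mthfd2 was at 4.33 log2 CPM in mutant replicate 4, against 4.77 to 4.82 in the other mutants. Aldh18a1 was at 3.31 in wild-type replicate 6, against 2.11 to 2.54. Stk32b was at 3.51 in wild-type replicate 1, against 4.02 to 4.21, and Perm1 at 2.49 in wild-type replicate 5, against 3.10 to 3.47. In mutant replicate 5 the NRF2 score was 0.10, against 0.31 to 0.33, and the p53 score 0.77, against 0.16 to 0.26. The ribosomal protein score was 0.30 in wild-type replicate 1, against -0.28 to -0.09, and the collecting duct score 0.69 in wild-type replicate 3, against -0.41 to 0.

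The first pattern is the rise of the 9 called stress response genes: Trib3, Atf5, Asns, Ddit3, Chac1, Slc7a5, Mthfd2, Aldh1l2 and Aldh18a1. RNA of the selected macrophages as the main carrier is argued against, but only weakly. Over the 4 mutant libraries the excess of these genes over the wild-type mean did not follow the macrophage score. The median slope was -0.06, and the range of -0.46 to 0.12 is between genes and is no error of the slope. The 15 macrophage markers had 1.3 in log2 CPM without subtraction. That is no independent benchmark, since the score is the mean of these markers. An unequal macrophage share between libraries is also argued against, since 9 of 9 genes stayed called with that score as covariate and their median log2 fold change went from 1.98 to 1.93. RNA of the ascending limb stays open, since the median slope on its markers was 0.37 with a range from -0.28 to 1.3, and tubule cells of other segments were not tested. Its score was 0, 0.34, -0.7 and -0.72 in mutant replicates 1, 2, 4 and 5, against -0.48, -0.51, 0.74 and 2.12 for macrophages. Both slopes thus set mutant replicates 1 and 2 against 4 and 5 and are not separate tests. The rise may therefore come largely from cells other than the selected macrophages, a hypothesis found and tested on the same 4 mutant libraries, and a response that differs between the macrophages of different mice is not excluded.

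The second pattern is the set of higher immune lists, 9 lists with a median log2 fold change of 0.70 between them once macrophage markers were left out. With the macrophage score as covariate this median was -0.03 (range -0.24 to 0.19), which is what an unequal share of macrophage RNA would give. Without mutant replicate 5, the library with the highest Adgre1, it was -0.17 (range -0.31 to 0.08), and without wild-type replicate 6, the wild-type library with the highest Adgre1, it was 1.18 (range 0.7 to 1.73), while the 8 other fits without 1 library gave 0.55 to 0.91. Among these 10 libraries the median thus depends on which library with a high macrophage share is kept. In wild type the macrophage score rose with the replicate number, from -1.54 in replicate 1 to 1.28 in replicate 6. Leaving out 1 high library therefore unbalances the groups. At each of the 4 shared numbers the mutant library had the higher score, by 1.05, 0.69, 0.91 and 1.7. If the numbers mark pairs, the pattern does not rest on mutant replicate 5 alone. An unequal macrophage share is a candidate explanation, and whether it came from the selection or from more macrophages in mutant kidneys was not tested.

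The third pattern is the fall of Umod and Egf. Dilution of tubule RNA by macrophage RNA is argued against: with the macrophage score as covariate both passed, with log2 fold changes of -1.84 for Umod and -2.54 for Egf. A loss of ascending limb and distal tubule RNA as the whole cause is argued against too: the other 12 markers had a median of -0.27 and ranged from -1.03 to 0.28, all above the fall of Umod at -2.03. With the score of these markers as covariate Egf stayed called at -2.17 (adjusted p = 0.00909) and Umod, not called with or without it, was at -1.42 (adjusted p = 0.0843), so a partial loss stays open. A lower level in cells that make mutant uromodulin is another possible explanation, and it was not tested here.

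Other splits of the 10 libraries were counted in 100 draws, the real split included. As many called genes as the real 30 came from 3 of the 100, and the highest other split called 1629. That share is under 0.05, but not all possible splits were drawn. Other groupings also called far more genes than the real one, so the count cannot decide whether chance is excluded. The other 2 splits set mutant replicates 1 and 2 with wild-type replicates 1 and 3 or 1 and 2 against the rest, and their 1629 and 1162 genes point to a structure of the samples. Both took their 4 libraries from the 5 with the lowest macrophage score, but 4 of the drawn splits did so and the fewest genes among these was 0, so that score alone does not set the count. For the integrated stress response list 1 of 100 splits, the real one, gave as small a camera p (-log10 p of 60.4, highest other 22.4). Among the splits drawn, chance is argued against for this list taken alone. For the number of called lists, 24, as many came from 16 of 100 splits with up to 29, so chance is not excluded.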

How the results depend on the processing

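The covariates for the macrophage and ascending limb scores, the fits without the 2 lowest-Adgre1 libraries of each group, of the 8 libraries with shared numbers and without Rn45s were chosen after seeing the data; all else was planned. The count of 30 called genes was 13 on single transcripts, 143 in DESeq2, 50 with the macrophage score and 13 without the lowest-Adgre1 libraries (6 of the 30 genes among them), and 14 to 24 when 1 library was left out; fewer libraries entered the last 2, and otherwise the cause was not tested. It lay between 26 and 43 in the other fits of all libraries. The labels do not say whether a replicate number marks a shared litter or day. The group mean of each gene was subtracted from its log2 CPM, and these deviations correlated between same-numbered libraries at 0.43, 0.28, 0.02 and 0.44. Not all were over 0.1, and not each mutant correlated best with its own number. The numbers were therefore not used as pairs in the main test, but these correlations cannot reject pairing. Adgre1 rose with the number in wild type, at 14, 27.5, 63.9, 102, 145 and 406 CPM in replicates 1 to 6. It was at 58.2, 58.6, 229 and 819 CPM in mutant replicates 1, 2, 4 and 5. The number may thus mark an order or a batch, which was not tested, and pairing is not excluded. A replicate block over 4 shared numbers gave 217 genes (193 rose, 24 fell, 28 of the 30 among them) and Umod at -2.27 (adjusted p = 0.0181), against 21 genes without the block in the same 8 libraries. Of the 24 lists called in the main fit, 3 lost their call with the block, and 3 did in the same libraries without it. With the block all 9 immune lists passed camera with the preset correlation, with a median log2 fold change of 1.01 between them, against 1.2 in the same libraries without it; the mutant library had the higher macrophage score at each of the 4 numbers, by 1.05, 0.69, 0.91 and 1.7, where an exact two-sided sign test cannot go under p = 0.125. Umod was lower in all fits, from -2.46 to -1.77 with 1 library left out, and passed in DESeq2 (-2.03), with the macrophage score (-1.84) and without the lowest-Adgre1 libraries (-2.95). The 24 called lists became 2 with an estimated correlation, 15 in limma-voom, 15 with the macrophage score, 11 with the ascending limb score, and 12 (without mutant replicate 5) to 26 with 1 library left out. The integrated stress response list passed camera in each setting run, with a median of 0.84 to 1.10. Called genes kept their call in 548 pairs of gene and setting and lost it in 169, with 0 reversals; named genes not called passed in 42 pairs and reversed in 40. Not run were sex as covariate, since all 10 libraries carried Y-linked RNA, and FPKM pseudocounts and filters, since counts were used. Depth limits genes such as Npffr2, with 30 to 81 counts per mutant library.

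Directions that reversed (for lists, camera's direction), given as list medians and gene log2 fold changes, were as follows, and the cause was not tested beyond the covariate itself. With the tubule score: lists phagocytic receptors -0.52, NF-kB genes -0.03, type I interferon -0.41, interferon gamma -0.31, MHC class II -0.71, complement -0.54, fibrosis-related genes -0.30, alternative activation -0.67, oxidative phosphorylation 0.16, macrophage markers -0.62, proximal tubule markers -0.07, genes Cd163 -0.46, Mrc1 -0.24, Ccl8 -0.11, Usp18 -0.12, Psmb8 -0.20, H2-DMb1 -0.45, H2-DMa -0.62, H2-Eb1 -0.65, C5ar1 -0.54, F13a1 -0.22, Clec10a -0.27, Apoe -0.06, Ms4a7 -0.05, Cd4 -0.40, Adgre1 -0.76. With the ascending limb score: lists phagocytic receptors -0.55, type I interferon -0.43, interferon gamma -0.23, MHC class II -0.69, complement -0.50, alternative activation -0.70, oxidative phosphorylation 0.23, macrophage markers -0.68, T cell markers -0.09, genes Cd163 -0.68, Mrc1 -0.25, Ccl8 -0.87, Usp18 -0.06, Psmb8 -0.12, H2-DMb1 -0.45, H2-DMa -0.60, H2-Eb1 -0.65, C5ar1 -0.50, F13a1 -0.13, Clec10a -0.42, Ms4a7 -0.13, Cd4 -0.37, Adgre1 -0.84. With the macrophage score: lists phagocytic receptors -0.03, type I interferon -0.14, interferon gamma -0.03, MHC class II -0.14, complement -0.03, oxidative phosphorylation 0.04, genes H2-DMb1 0, H2-DMa -0.10, H2-Eb1 -0.10, Adgre1 -0.09. Without mutant replicate 5: lists type I interferon -0.20, oxidative phosphorylation -0.01, genes Psmb8 -0.01, H2-DMb1 -0.07, H2-DMa -0.12, H2-Eb1 -0.14, C5ar1 -0.34, Adgre1 -0.13. The other end of the range with 1 library left out came without wild-type replicate 6: type I interferon 1.08, Psmb8 1.25, H2-DMb1 1.64, H2-DMa 1.70, H2-Eb1 1.70, C5ar1 2.05, Adgre1 2.05. On single transcripts: genes Relb -2.88.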

Other observations

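Markers of erythroid cells were uneven between libraries. Alas2, the first enzyme of heme synthesis in erythroid cells, had 3.38 ± 2.24 CPM in mutants (SD, n = 4) and 21.0 ± 22.5 CPM in wild type (SD, n = 6), with a log2 fold change of -2.63 (SE 0.912, edgeR adjusted p = 0.701). Cyp51, a sterol demethylase of cholesterol synthesis, had 110 ± 13.5 CPM in mutants and 187 ± 43.3 CPM in wild type, each mutant library below each wild-type library, with an edgeR adjusted p of 0.209; it was the 1 member of its list that passed when adjusted over the list alone. Pdk1, a kinase that restrains pyruvate oxidation, had a log2 fold change of -0.49 (SE 0.158, edgeR adjusted p = 0.648), again with all mutant libraries below all wild-type libraries.

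If macrophages themselves differed between genotypes, the mutant effect of some genes would grow with the macrophage share of a library. This test and its bound were set before its result was seen; the simulation of its power was added after. The interaction of genotype and macrophage score passed for 0 of 15123 genes in edgeR, with 650 at an unadjusted p under 0.05 where 756 would come by chance, and no other tool was run. On simulated counts of 15123 genes the test recovered 75.5% of 200 genes with a slope of 1 log2 unit per score unit, under the 80% then asked for to call the hypothesis excluded, and the fit had 6 residual degrees of freedom. The simulation set these slopes directly and does not cover genes expressed by macrophages alone. The bound of fewer than 10 genes, written as evidence against the hypothesis, was therefore too weak to decide, and macrophage effects of any size stay open.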
